A study of Mus musculus with 2 samples.

How the data were processed

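H3K9me3 ChIP-seq had been done on 2 pools of mouse facial prominences at embryonic day 11.5, replicate 1 from 109 and replicate 2 from 88 embryos, per the labels. Both replicates formed 1 group, so no comparison between groups and no pairing of samples was made. Per the labels, replicate 2 combined technical replicates 1 and 2 and was read on more than 1 instrument model. The assembly was mm10 per the labels, and the aligner and peak caller are not given in the sources used here.

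The authors deposited 4 peak lists. Per the deposited readme files, the replicate 1 list was made from its alignment and 2 further files, the replicate 2 list from its alignment and 1 of those 2, the pooled list from both alignments and the 2 further files, and the replicated list from the other 3 lists by a rule that is not stated. The further files are taken to be control libraries. Column 7 of each deposited list is the signal value of the peak over its control, as the authors' caller gave it. The deposited −log10 p and −log10 q of each peak are in 2 more columns, and the lowest −log10 p was 2.02 or higher in every list, so that the lists reach down to weak peaks. The last column is the summit position within the peak. Signal values of different lists were not compared, because the further files differ between lists and depths are not known. Reads were not used here, so each interval covers counting error of peaks or genes only.

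Coordinates were checked against the GRCm38.p6 reference, whose chromosome lengths all peak ends fit, and gene models were taken from GENCODE release M21 (21938 protein-coding genes on chromosomes 1 to 19, X and Y). Peaks on unplaced and unlocalized contigs entered the overlaps of lists and were left out of gene, chromosome and window analyses. A gene held a peak when the 2 overlapped by at least 1 bp between annotated start and end.

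The main test moved all peaks of a list together by a random offset along the concatenated circular chromosomes, with runs of unknown bases of 10 kb or longer removed (2648 Mb), 10000 times with a fixed seed. This keeps the spacing and widths of peaks and the places and lengths of genes. The two-sided p is 2 times the smaller tail, with a lower limit of 0.0002. Benjamini-Hochberg adjustment was made over the 17 gene lists. A moved peak can land in sequence where reads cannot be placed, so moved counts are somewhat low. Signal values of shared and other replicate 1 peaks were compared by permutation with 100000 draws, the last exon by placing each summit at random along its gene 100000 times, sequence content by 1000 moved sets, and clustering by independent random placement 10000 times. Shares have Wilson 95% intervals and densities exact Poisson 95% intervals. Copies in the reference were counted for all 24-base words of a peak on both strands, and their median was taken. A stricter set kept only peaks in which every word occurred once.

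The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Zinc finger, receptor, protocadherin, HOX, histone, ribosomal, keratin-associated, P450 and testis lists were defined by gene symbol, so the zinc finger list can hold a few genes of another zinc finger class and leaves out C2H2 genes with other symbols, such as the Krüppel-like factors (Klf14 among them), and genes with a letter after the Zfp number, of which Zfp354c held 2 replicated peaks. Of the imprinted genes listed, 6 are not protein-coding in the annotation under that symbol, and of the H3K9 methylation and reader genes 1. Genes were named by this rule: the 20 protein-coding genes with the strongest replicated peaks, up to 4 genes per list with the strongest peak, the 10 fullest windows with up to 3 genes each, and the 5 strongest peaks outside annotated genes. Genes named beyond it were chosen after their values were seen. They were Ddx4, Smc1b, Snrpn, Snurf, Sfi1, Drg1, Zfp354c, Pcdhga5, Pcdhgb1, Pcdhgb2, and those of the scan of gene families. Alternatives were other peak lists, stricter thresholds, other overlap rules, each replicate alone, chromosomes without X and Y, moves within chromosomes, wider gene bodies, and Fisher's exact test.

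The moved-peak test was tested on simulated data over the 21938 genes, with groups of neighbouring peaks placed at random and 500 moved sets each. With no effect, 5 of 340 list tests (1.47%) had p under 0.05. With a peak added to 20% of the members of the zinc finger, imprinted and craniofacial lists, all 20 of 20 simulations passed for each list. The simulated groups could lie anywhere, as the test assumes, so the error rate for peaks as uneven as the real ones was not measured. Many lists expect about 1 gene or fewer, which can keep the rate low. Effects weaker than 20% of members were not tried. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.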

Results

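Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of condensed and silenced chromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominences of mouse embryos at embryonic day 11.5. The facial prominences are the paired outgrowths that form the face. The samples made up 1 group with 2 biological replicates, of which replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos. With a single group, the comparisons concerned the agreement of the replicates and the places in the genome where peaks lay. Peak lists were deposited for each replicate, for both replicates pooled, and for replicated peaks. The replicate 1 list held 19722 peaks and the replicate 2 list 2324, while the pooled list held 6077 and the replicated list 2653. Median peak widths were 225 bp, 237 bp, 261 bp and 340 bp in the same order. Peak lists give no read totals, so the sequencing depth of either replicate is unknown here. Few peaks were strong by the authors' own statistics: 468 of the 2653 replicated peaks (17.6%) had a −log10 q of at least 2, and 157 (5.92%) of at least 5. Signal values and −log10 q are the authors' values for each peak, carry no error, and were ranked within 1 list only.

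The first comparison asked how far the replicates gave the same peaks. On chromosomes 1 to 19, X and Y, 1161 of the 2184 replicate 2 peaks overlapped a replicate 1 peak, a share of 53.2% (Wilson 95% interval 51.1 to 55.2%). When the replicate 2 peaks were moved together to random places, a mean of 8.85 peaks overlapped, 131 times fewer (permutation test, two-sided p = 0.0002, the smallest that 10000 moved sets can give). Counted from the longer list over all sequences, 1219 of 19722 replicate 1 peaks (6.18%, interval 5.85 to 6.53%) met a replicate 2 peak. Counted from replicate 2, the share depended on the threshold. Among peaks with a −log10 q of at least 2 in each list, 94 of 98 replicate 2 peaks (95.9%) were shared. When as many top peaks by −log10 p were taken from each list the share was 27.8%. It was 28.3% when the overlap had to cover at least 50% of both peaks. Counted from replicate 1 over all sequences, agreement stayed low at a −log10 q of at least 2 in each list: 126 replicate 1 peaks were shared and 1889 were not.

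Replicate 1 peaks that were found again in replicate 2 were the stronger ones. Their median signal value was 3.60 against 3.05 for the 18503 others, a difference of 0.548 (permutation test with 100000 draws, two-sided p = 2e-05, the smallest it can give). Peaks were shuffled singly although they cluster, so that neighbouring peaks count separately. In the highest decile of signal value 23.5% of replicate 1 peaks were shared (Wilson 95% interval 21.7 to 25.4%), against 7.61% in the ninth decile and 1.93% in the second, the lowest of all. The share did not rise steadily: the lowest decile stood at 5.17% (4.28 to 6.24%), above the values of deciles 2 to 7, some of which have overlapping intervals. Equal signal values were split between deciles by their order in the genome. With deciles of −log10 p instead, the lowest stood at 2.03% and the highest at 28.6%. Among peaks with a −log10 q of at least 2 in each list, the difference in medians was 0.110 and did not pass the test (permutation test, p = 0.419, 126 shared and 1889 other peaks).

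**Figure D1:**
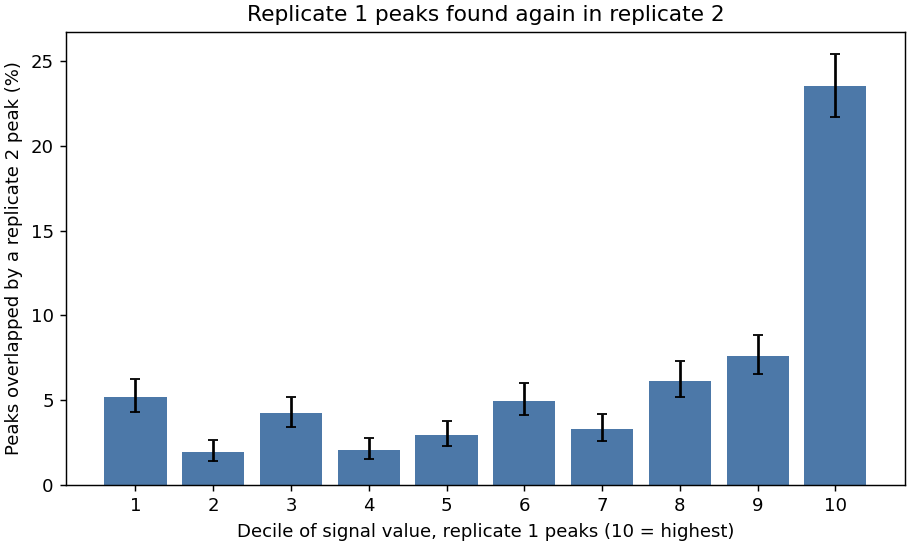
Percent of replicate 1 peaks overlapped by a replicate 2 peak (y axis) in each decile of the replicate 1 signal value (x axis, 10 the highest), with Wilson 95% intervals as error bars. The highest decile stands at 23.5%, above the 7.61% of the ninth decile.

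All 2653 replicated peaks were identical to a peak of the pooled list. Of these, 2365 (89.1%) overlapped a replicate 1 peak and 1270 (47.9%) a replicate 2 peak. Both replicate lists held a peak at 1110 of them (41.8%, Wilson 95% interval 40.0 to 43.7%), replicate 1 alone at 1255, replicate 2 alone at 160, and neither list at 128. A replicated peak was therefore not always a peak called in each replicate. If the overlap had to cover at least 50% of the replicated peak, the share found in both lists was 27.5%.

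The strongest replicated peak lay in the body of Klf14, within 1 kb of its start site. Klf14 is an imprinted gene for a Krüppel-like transcription factor. The peak covered positions 30956901 to 30958665 of chromosome 6 (mm10), had a signal value of 10.95 and a −log10 q of 23.9, and was found in the replicate 1 list (signal value 10.4) and the replicate 2 list (signal value 9.69). The next was within 1 kb of a start site of Tcfl5, a transcription factor gene on chromosome 2 (signal value 8.42), with a peak in replicate 2 and none in replicate 1. Genes near the end of the X chromosome were also among the strongest: Asmt, which encodes the last enzyme of melatonin synthesis (signal value 7.78, intron), Mid1, a ubiquitin ligase gene (signal value 7.40, last exon), and Gm21887 (signal value 7.03, start site). Genes of the zinc finger list made up 6 of the 20 genes with the strongest peaks: Zfp981 (signal value 6.96), Zfp873 (6.77), Zfp180 (6.16), Zfp146 (5.75), Zfp930 (5.75) and Zfp763 (5.63). The peak assigned to Ccdc106 (signal value 7.40) also lay in an exon of the zinc finger gene Zfp865. The remaining genes of the 20 were Smok2a, Gm37013, Cdkn1c, Tmcc1, Spred2, Arl5a, Habp4 and Trim71, with signal values from 6.57 to 5.08. Of the 20, 19 had a peak anywhere in the gene body in replicate 1 and 20 in replicate 2, which need not be the same peak. The strongest replicate 2 peak of each gene had a −log10 q from 0.0 (Habp4) to 16.5 (Gm21887).

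Genes for C2H2 zinc finger proteins, a large family of DNA-binding proteins that lies in clusters, held replicated peaks far more often than moved peaks gave. Of 441 such genes, 69 (15.6%) had a peak in the gene body, against a mean of 7.85 for moved peaks, an 8.79-fold difference (permutation test, p = 0.0002, the smallest possible, adjusted p = 0.0017 over 17 lists). These genes held 172 distinct peaks in 44 windows of 1 Mb. The replicate 2 list alone had 60 of the genes and the replicate 1 list alone 145, of which 52 were in both. In the replicate 1 list the fold was 2.51, and in replicated peaks with a −log10 q of at least 5, which met 7 of the genes, it was 24.2. Both passed the permutation test at p = 0.0002. With exons in place of gene bodies, an alternative chosen after seeing the data, the fold was 22.1 with 54 genes.

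Within these genes the peaks lay towards the last exon, which encodes the zinc finger array in most of them. Of 171 peak summits in 68 zinc finger genes, 72 (42.1%, Wilson 95% interval 35.0 to 49.6%) fell in the last exon of the longest transcript. Summits placed at random along the same genes gave 17.4% (permutation test with 100000 draws, two-sided p = 2e-05, the smallest possible). Each summit was placed on its own, so that neighbouring peaks of 1 gene count separately. Random places could also fall in introns where reads cannot be placed, so the random share can be somewhat low. With only the strongest peak of each gene, an alternative chosen after seeing the data, 35 of 68 summits (51.5%, interval 39.8 to 63.0%) lay in the last exon against 18.3% at random (permutation test, p = 2e-05). Examples are the strongest peaks of Zfp873, at 82060448 to 82061493 of chromosome 10, and of Zfp180, at 24104081 to 24107498 of chromosome 7.

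Of 50 imprinted genes in the annotation, which are expressed from the copy of 1 parent, 25 held a replicated peak against a mean of 1.68 for moved peaks (14.9-fold, permutation test, p = 0.0002, adjusted p = 0.0017). The 47 peaks lay in 18 windows of 1 Mb, since neighbours such as Snrpn and Snurf share peaks. A replicated peak lay within 1 kb of a start site in 20 of the 50 genes, among them Cdkn1c, a cell cycle inhibitor (signal value 5.50), Impact (4.61) and Grb10, a growth factor receptor adaptor (4.51). In the replicate 1 list alone 34 of these genes had a peak and the fold was 3.07, and in replicate 2 alone 17 had one and the fold was 10.8.

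The clustered protocadherins, cell surface proteins of neurons, held peaks in 37 of 57 genes, against a mean of 2.64 for moved peaks (14.0-fold, permutation test, p = 0.0006, adjusted p = 0.0034). Their 84 distinct peaks lay in 2 windows of 1 Mb on chromosome 18. The genes of the alpha and gamma groups are annotated as nested models over a shared end, so that 1 peak counts for several of them, and the list is in effect 1 locus. At a −log10 q of at least 5 the fold was 193.0, and all 17 genes left were nested models of the gamma group. In the later scan of gene families the Pcdhb genes did not pass after adjustment (88.3-fold, permutation test, adjusted p = 0.0680). Nor did the Pcdhga genes (15.1-fold, permutation test, unadjusted p = 0.0854) or the Pcdha genes (9.59-fold, permutation test, unadjusted p = 0.173). Each replicate list on its own met 37 or more of the genes, 49 in replicate 1, where the fold was 2.94, and 37 in replicate 2. The strongest peak of the cluster covered 37694308 to 37696923 (signal value 6.26). It lay over the annotated start of Pcdhga5, at 37694380. It also fell within the bodies of the models that begin upstream, Pcdhga1, Pcdhga2, Pcdhga3, Pcdhga4, Pcdhgb1 and Pcdhgb2.

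**Figure D2:**
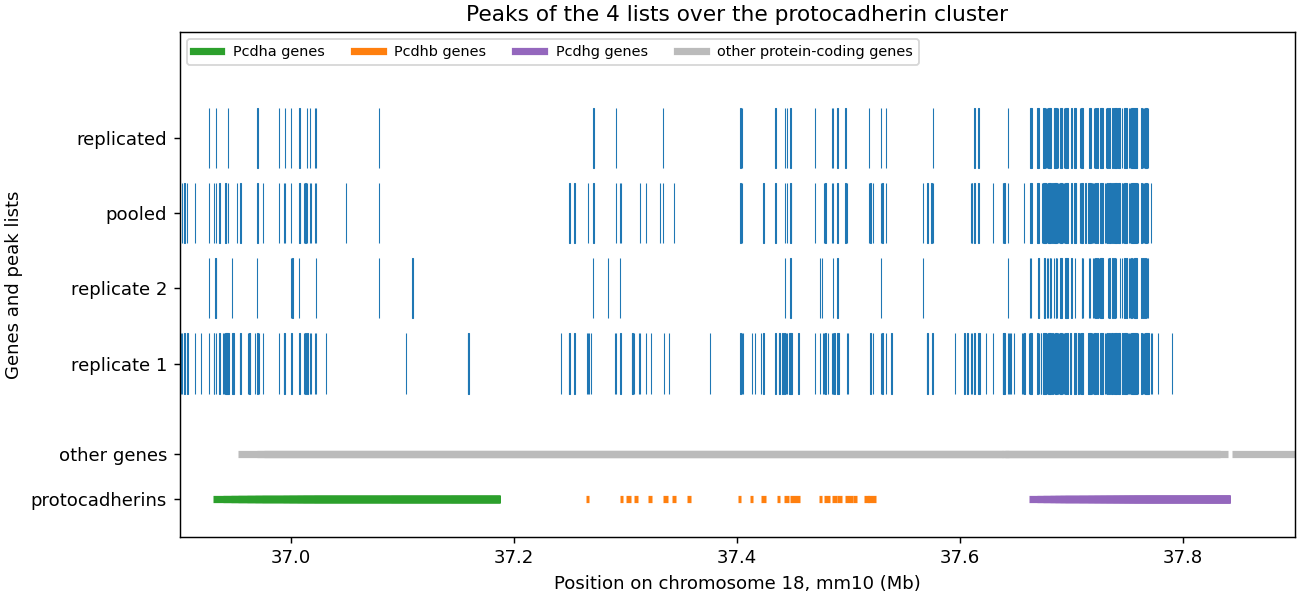
Map of the protocadherin cluster on chromosome 18 (x axis, position in Mb, mm10), with peaks of the replicate 1, replicate 2, pooled and replicated lists as blue bars of their true width, protocadherin genes coloured by group, and other protein-coding gene models in grey. In all 4 lists peaks are densest over the gamma group, and the long grey models include Gm37013.

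**Figure D3:**
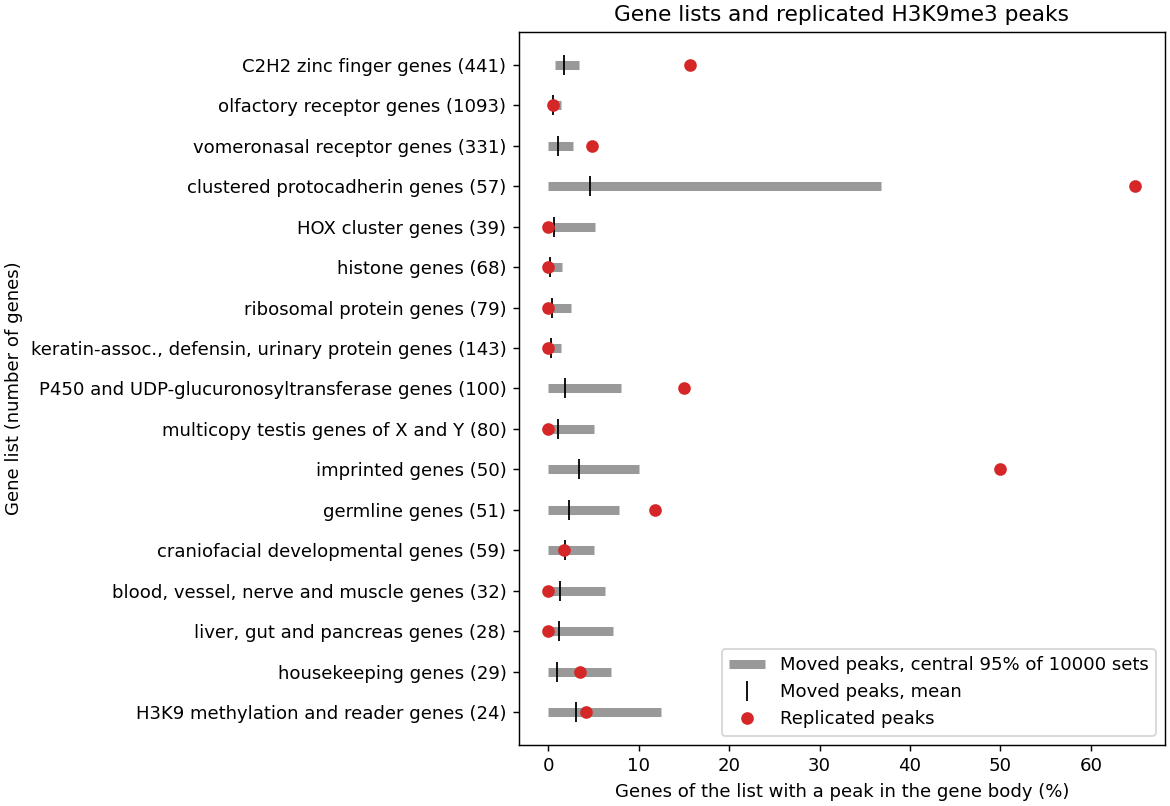
Percent of the genes of each list with a replicated peak in the gene body (x axis, red points), for the 17 lists (y axis, with their number of genes). Grey bars are the central 95% of 10000 sets of moved peaks and black ticks their mean. Clustered protocadherin genes (64.9%) and imprinted genes (25 of 50) lie farthest to the right.

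Other lists were also called higher. Of 100 cytochrome P450 and UDP-glucuronosyltransferase genes, which serve the metabolism of drugs and steroids, 15 held a peak against a mean of 1.88 (7.96-fold, permutation test, p = 0.0016, adjusted p = 0.0068), and 9 of the 15 were the overlapping Ugt1a genes of chromosome 1. Germline genes, normally used in sperm and egg precursors, held a peak in 6 of 51 cases (5.26-fold, permutation test, p = 0.002, adjusted p = 0.0068). They were Dazl (signal value 4.49), Meioc (3.98), Nlrp5 (3.98), Taf7l (3.35), Ddx4 and Smc1b, and all 6 had a replicated peak within 1 kb of a start site. In the replicate 2 list alone the germline list no longer passed (4 genes, 3.78-fold, permutation test, adjusted p = 0.123), nor did it for replicated peaks found in both replicate lists, an alternative chosen after seeing the data (3 genes, 6.25-fold, permutation test, adjusted p = 0.0810). Vomeronasal receptor genes, which encode pheromone receptors, held a peak in 16 of 331 cases (4.62-fold, permutation test, p = 0.0044, adjusted p = 0.0125). That call was lost when peaks were moved within their chromosomes (2.51-fold, permutation test, adjusted p = 0.155), by Fisher's exact test against other genes (1.54-fold, adjusted p = 0.174), and for replicated peaks found in both replicate lists, the alternative chosen after seeing the data (6 genes, 4.22-fold, permutation test, adjusted p = 0.0810). Among replicated peaks with a −log10 q of at least 5, neither germline nor vomeronasal receptor genes held a peak, but moved peaks gave means of only 0.0427 and 0.131, so that this threshold says nothing about either call.

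Of the lists that did not pass, olfactory receptor genes had peaks in 6 of 1093 genes against a mean of 5.61 for moved peaks (permutation test, adjusted p = 1.0). By Fisher's exact test against other genes the list was called lower instead (0.166-fold, adjusted p = 9.82e-09). That test takes no account of the lengths and places of genes, which moved peaks keep. Craniofacial developmental genes, the list closest to the tissue, had a peak in 1 of 59, Six4 (signal value 3.09 and −log10 q of 0.0257), against a mean of 1.08. Housekeeping genes had a peak in Tbp alone, 1 of 29, and genes of H3K9 methylation and its readers in Setdb1 alone, 1 of 24, with a −log10 q of 0. No replicated peak met the 39 HOX cluster genes, 68 histone genes, 79 ribosomal protein genes, 143 keratin-associated, defensin and major urinary protein genes, 80 multicopy testis genes of X and Y, 32 genes of blood, vessel, nerve and muscle cells, or 28 liver, gut and pancreas genes. Moved peaks gave a mean below 1 in each of these 7 lists, so that fewer peaks than by chance could not have been detected.

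Across the genome, 694 of 21938 protein-coding genes (3.16%) held a replicated peak in the gene body, 519 of them outside the 17 lists. A replicated peak lay within 1 kb of a start site of 182 genes, against a mean of 90.9 for moved peaks (2.00-fold, permutation test, p = 0.0002, the smallest possible). The fold was 1.32 in the replicate 1 list (permutation test, p = 0.002) and 3.62 for replicated peaks with a −log10 q of at least 5. Among the 182 genes were 25 clustered protocadherins of 1 locus, 20 imprinted, 16 zinc finger and 6 germline genes, and a gene can be in more than 1 list. Moved peaks were not matched for GC content. The excess was therefore not shown to be a trait of start sites in general. Peak centres fell in protein-coding gene bodies in 42.5% of cases against 39.2% for moved peaks, which was within the range of moved peaks (33.4 to 45.2%, permutation test, p = 0.276).

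Replicated peaks on chromosomes had a GC content of 49.5% against 41.7% for moved peaks, and 20.0% of their bases were soft-masked as repeats in the reference against 36.4% (permutation test with 1000 moved sets, p = 0.002 for each, the smallest possible). Of 2484 peaks on chromosomes, 2423 (97.54%, Wilson 95% interval 96.9 to 98.1%) lay in sequence whose 24-base words typically occurred once in the reference, against 81.8% of the same peaks moved along their chromosomes. Peaks can be called only where reads can be placed, while moved peaks can land in repeats where reads cannot be placed. The lower share of repeat bases therefore cannot be read as the mark avoiding repeats.

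Chromosome 7 carried the most peaks per Mb, 2.71 (exact Poisson 95% interval 2.45 to 2.999), against 0.938 over all chromosomes. Chromosomes 17 and 18 followed with 1.78 (1.51 to 2.07) and 1.75 (1.48 to 2.05). The X chromosome had 0.232 (0.165 to 0.319) and the Y chromosome 0.0340 from 3 peaks (0.00702 to 0.0995). These intervals cover counting error only, and peaks cluster, so no test was made between chromosomes. Densities were not adjusted for the copy number of X and Y or for sequence where reads cannot be placed. The low values there therefore cannot be read as scarcity of the mark.

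**Figure D4:**
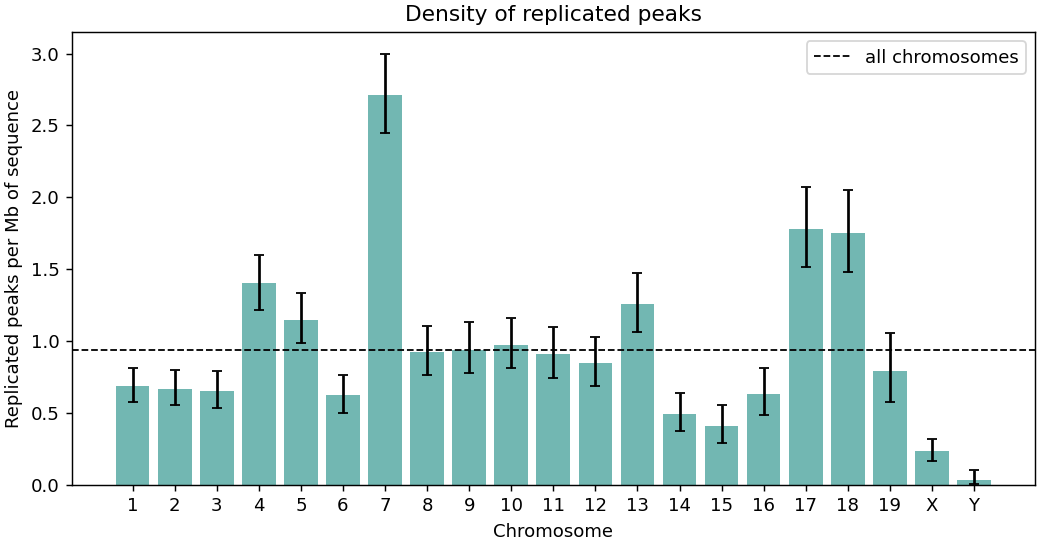
Replicated peaks per Mb of sequence (y axis) on each chromosome (x axis), with exact Poisson 95% intervals as error bars and the value for all chromosomes as a dashed line. Chromosome 7 has the highest bar, 2.71 peaks per Mb, and the Y chromosome the lowest, 0.0340.

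The 20 fullest windows of 1 Mb held 23.2% of the replicated peaks, against 3.56% for peaks placed independently at random (permutation test, p = 0.0002, the smallest possible). The share was 8.69% against 1.62% in the longer replicate 1 list, and 80.7% against 20.4% for the 109 replicated peaks on chromosomes with a −log10 q of at least 5. In the order given, the folds over random placement were 6.50, 5.36 and 3.97. The fullest window, from 37000001 to 38000000 of chromosome 18, held 91 peaks over the protocadherins, most of them within the long gene models Gm37013, Gm42416 and Gm37388. The window from 88000001 of chromosome 1 held 48, of which 24 met Trpm8, a cold-sensing channel gene, 12 met Mroh2a and 8 met Ugt1a7c. The window from 12000001 of chromosome 7 held 41, with Zfp110, Zfp606 and Vmn2r53 leading. On chromosome 10 the window from 82000001 held 32, of which 11 met Zfp873, with Gm4924 and AU041133 next. On chromosome 17 the window from 13000001 held 28, with 5 in Smok2b and 4 in Smok2a, genes for sperm kinases. Further windows on chromosome 7 began at 10000001 (26 peaks, Vmn1r68, Vmn1r70 and Nlrp4b) and 6000001 (23 peaks, Peg3, Gm20715 and Galp), and on chromosome 4 at 147000001 (24 peaks, Zfp933 and Zfp982). Windows from 3000001 of chromosome 3 (34 peaks) and 33000001 of chromosome 7 (29 peaks) held no protein-coding gene with a peak.

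Outside annotated genes, the strongest replicated peak lay at 3271678 to 3272336 of chromosome 16 (signal value 7.48), 318.7 kb from Olfr161. Others were at 12010267 to 12010965 of chromosome 7 (5.99, nearest gene Vmn1r77), 3055703 to 3056519 of chromosome 4 (5.63, nearest Vmn1r2), 173562708 to 173563120 of chromosome 1 (5.50, nearest Ifi213) and 90738743 to 90740606 of chromosome Y (5.45, nearest Gm21860), each value being the signal value. All 5 overlapped a peak in both replicate lists.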

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

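The tests of single libraries, of control files, of lower power and of missing copies were chosen after the results were seen. The tests of shared reads and of background calls were chosen after the main results, and their limits were set before their own values were seen. No biological explanation was tested for these patterns, because the design holds 1 group.

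Sequence outside the chromosomes, which no gene analysis used, held 169 replicated peaks, 6.37% of the list. That is 31.7 peaks per Mb of unplaced and unlocalized contigs (exact Poisson 95% interval 27.1 to 36.8), 33.8 times the 0.938 per Mb of the chromosomes, and the peaks lay on 16 of 44 contigs. Both replicate lists showed it, with ratios of 6.58 in replicate 1 and 31.8 in replicate 2. A candidate explanation is that copies of these sequences are missing from the assembly, so that reads from many copies gather on 1, which raises −log10 p more than the signal value. The share leans that way: 60.4% of the contig peaks (Wilson 95% interval 52.8 to 67.4%) had a lower signal value than the median of the 20 chromosome peaks nearest in −log10 p. The interval takes the peaks as independent, but 40 of the 169 lay on 1 contig and 37 on another. The excess over 50% is modest, so the test cannot decide, and real enrichment on the contigs stays open.

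More zinc finger genes held a replicated peak than moved peaks gave. Reads shared between paralogs are argued against as the whole cause: the 654 replicated peaks in which every 24-base word occurred once in the reference met 23 of the 69 genes, an 8.65-fold excess over the same peaks moved (permutation test, p = 0.0002, the smallest possible). Only exact copies were counted, so near copies, and a part played by shared reads in the other 46 genes, stay open. Calls of 1 library only are also argued against, since the lower of the folds in the 2 replicate lists was 2.51 and passed the test. GC content, which was higher in peaks than in moved peaks, and the control libraries were not tested as causes and stay open.

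The replicate 1 list was 8.49 times as long as the replicate 2 list. Background calls alone are argued against as the content of the extra peaks: the 14919 replicate 1 peaks absent from the replicate 2 and pooled lists still gave a 2.14-fold excess of zinc finger genes (permutation test with 1000 moved sets, p = 0.002, the smallest possible), which does not exclude that many of them are background. Lower power of the replicate 2 library stays open. Strong replicate 1 peaks were shared more often over the whole list, which weak background calls in replicate 1 would give as well, and among peaks with a −log10 q of at least 2 in each list the difference in median signal was 0.110 and did not pass (permutation test, p = 0.419). Different control files cannot be told apart from the replicates, because replicate 1 had 1 control file that replicate 2 did not.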

How the results depend on the processing

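Of 70 alternative values for the main results, 67 were counted as kept, as were 325 of 361 for single gene lists, the Ceacam family and named genes. Kept meant the same direction and side of the threshold, or a value within the main value's interval, with exceptions. A list that did not pass in the main setting was kept if it failed again, whichever way its fold lay. Craniofacial genes, for example, went from 0.928-fold to 2.00-fold in the replicate 2 list. The number of lists called higher, 6 in the main setting, was kept at any value from 4 to 6, although single lists lost their call. Of the rest, 27 moved, all of them named genes without a peak under the alternative, and 6 lost their call. The other 3 were counted as turned by these rules, of which 2 are counts of 0 where under 1 gene was expected. Part of the 325 was fixed in advance, since the pooled list holds every replicated peak and so a peak in all 46 named genes. The 7 lists without a replicated peak had moved means below 1 and little room to change. The Zfp family was not counted, and its adjusted p went from 0.0255 to 0.051 when peaks were moved within chromosomes (permutation test). Alternatives chosen after the data were seen were peaks found in both replicate lists, single-copy peaks, peaks with every 24-base word found once, exons in place of gene bodies, RefSeq zinc finger products, the strongest peak of each gene for the last exon, and moves within chromosomes for the Ceacam genes. The single-copy filter removed no gene with a peak from any list, so it says nothing about their stability. Over the 12 settings of the gene list test, zinc finger genes (2.51 to 24.2-fold), imprinted genes (3.07 to 49.0-fold), clustered protocadherins (2.94 to 193.0-fold) and P450 and UDP-glucuronosyltransferase genes (2.05 to 134.3-fold) passed in all 12 settings, and 4 to 6 of the 17 lists were called higher. The 193.0-fold and 134.3-fold each rest on 1 locus: 17 nested gamma protocadherins and 9 overlapping Ugt1a genes at a −log10 q of at least 5. Over 255 families scanned by symbol, neither Cyp (4.21-fold, permutation test, adjusted p = 0.788) nor Ugt genes (14.0-fold, permutation test, adjusted p = 0.357) nor any protocadherin family passed alone. Folds were lower in the longer replicate 1 list, where moved peaks meet more genes. Among peaks with a −log10 q of at least 2 in each list, the signal difference of shared peaks was 0.110 (permutation test, p = 0.419), with 2015 replicate 1 peaks left. With at least 50% of the replicated peak covered, 27.5% were found in both lists. The density of chromosome 7 over that of all chromosomes, 2.89 in the main list, ranged from 2.14 to 2.63 with 1 replicate left out, and the cause was not tested. Vomeronasal receptor genes and germline genes had a fold of 0.0 at a −log10 q of at least 5, where 109 peaks were left and moved peaks gave means of 0.131 and 0.0427, so a count of 0 was expected and is no change of direction. For peaks found in both replicate lists they had folds of 4.22 and 6.25 and did not pass (permutation test, adjusted p = 0.0810 for each), with 6 and 3 genes left. Olfactory receptor genes turned to 0.166-fold by Fisher's exact test (adjusted p = 9.82e-09), against 1.07-fold for moved peaks. That test ignores gene lengths and places, unlike moved peaks, and which of these mattered was not tested. Of the 46 genes named for the strongest peaks or from the lists, 43 kept a peak in each replicate list alone and 25 at a −log10 q of at least 5. Genes named only for the fullest windows were not checked in this way. Unknown read depth limits any statement on the absence of peaks. No paired analysis was possible because the design holds 1 group.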

Other observations

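The scan of gene families, the tests of the first Mb of chromosomes and the values below were chosen after the data were seen. In a scan of 255 families of 10 or more protein-coding genes with the same symbol stem, 2 held more genes with a replicated peak than moved peaks gave after adjustment over the families. Besides the Zfp genes, these were the Ceacam genes, cell adhesion molecules of the immunoglobulin class: 6 of 15 held a peak against a mean of 0.137 for moved peaks (permutation test, p = 0.0002, adjusted p = 0.0255), with 8 of the 15 met in replicate 1 and 3 in replicate 2. They were Ceacam3, Ceacam5, Ceacam12, Ceacam13, Ceacam14 and Ceacam20, and all 6 lie between 17150282 and 19991104 of chromosome 7, the chromosome with 2.89 times the overall density. When peaks were moved within their chromosomes the Ceacam fold fell from 43.9 to 14.6 and did not pass after adjustment (permutation test, p = 0.003, adjusted p = 0.383), and no family passed. The Zfp genes had a 6.54-fold excess at the smallest possible p of 0.0002, which over 255 families gives an adjusted p of 0.051. Among Nlrp genes, 5 of 17 held a peak (10.9-fold), which did not pass after adjustment (permutation test, adjusted p = 0.140).

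On the X chromosome, 20 of 38 replicated peaks (52.6%) lay in the last 2 Mb, where Mid1, Gm21887 and Asmt lie. The replicate 2 list had 17 of its 33 X peaks there, and replicate 1 had 27 of 351. No test was made of this region.

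Several of the fullest windows open a chromosome. The first Mb of sequence of the 21 chromosomes held 146 replicated peaks against a mean of 19.7 for moved peaks (7.41-fold, permutation test, p = 0.0008), but that count includes the windows that drew attention to it, on chromosomes 3 (34 peaks), 16 (21 peaks) and 4 (20 peaks). On the other 18 chromosomes the first Mb held 71 peaks against a mean of 17.4 for peaks moved within chromosomes (4.08-fold, permutation test, p = 0.0268), with a fold of 2.56 in replicate 1 (p = 0.0088) and 4.05 in replicate 2 (p = 0.035). The excess is uneven: 12 of the 18 had any such peak, and chromosome 11 held 15, chromosomes 10 and 17 12 each and chromosome 18 10. Of the 15 on chromosome 11, 8 lay in the short stretch over Sfi1 and Drg1 that is described below. Its cause was not tested.

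Between 3184196 and 3200112 of chromosome 11, over Sfi1 and Drg1, 8 replicated peaks had a −log10 p of 23.5 to 54.9, the highest of the list, with signal values of only 2.26 to 3.56. Of the 20 replicated peaks with the highest −log10 p, 10 lay on unplaced contigs and 9 had a signal value below the median of the list, 3.35. The window from 88000001 of chromosome 1 held 75 replicate 2 peaks against 72 replicate 1 peaks, although the replicate 1 list is the longer one.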
